A study of Homo sapiens with 4 samples.

How the data were processed

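Total RNA of CFL1 knockout and control cells, labelled PANC-1, was sequenced on an Illumina NovaSeq 6000, per the labels' protocols, which state that RNA with an integrity number of at least 7 was used. The submitters' processing notes name cutadapt, FastQC, STAR, RSEM and the genome build hg19, with no versions and no order. Gene identifiers in the deposited table follow the GENCODE annotation lifted to that build. No coordinates are given, because the annotation used here belongs to another build.

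The 1 file is the authors' DESeq2 result table of CFL1 knockout against control. Its base mean is a signal, the mean over all 4 libraries of counts divided by size factors, as deposited by the authors. The log2 fold change and its standard error are on the log2 scale and were fitted by the authors without shrinkage, since values reach -28.03 for GJA1 in the authors' deposited table. The Wald score is the fold change divided by its standard error, as the authors deposited it. The deposited p-value columns hold the unadjusted p and the Benjamini-Hochberg adjusted p, which the authors' table gives for 16629 genes, the lowest base mean among them being 12.5. The table's mark for up- or downregulated genes equals an unadjusted p under 0.05 for all 2349 marked genes.

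The table holds no values per library, so the calls are the authors' adjusted p under 0.05, as the design had set for such a table before the data were examined. Gene lists, 35 in number and written before the data were examined, were tested with cameraPR of limma 3.58.1 (R 4.3.3) on the authors' Wald score with a preset correlation of 0.01, for lists of at least 5 measured members, with Benjamini-Hochberg adjustment over 34 lists. CFL1 is in no list. The result of 1 list, which is among the 16 called, is not reported here. Named genes are CFL1; the 10 largest rises and falls among called genes with at least a 2-fold change and a base mean of at least 100, with both knockouts on the same side of both controls; the 3 most abundant called genes in each direction; up to 3 rising and 3 falling called members of each list, or its most abundant member where none is called; and METTL3, YTHDC2, KMT2A and MYC. LPL was chosen after its values were seen.

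Reads per library were recovered after the data were seen. A base mean printed to 15 digits is the sum over 4 libraries of whole reads times a step, and the 4 steps are the base means of genes with 1 read in 1 library. The whole numbers that give a base mean within its printed digits were enumerated, with the deposited fold change used to narrow the search at high base means. The group of each library came from the sign of the authors' contrast for genes with 1 read. Whole reads came out for 30657 of 30831 genes (99.4%). At base means of at least 10, the fold change that the reads imply lay within 0.001 log2 of the deposited one for 17074 of 17136 genes. Base means were also shifted on purpose, and solutions were counted whose implied fold change lay within 0.001 log2 of the deposited one. Genes with a single solution were kept without this condition. Below a base mean of 10000, 6 of 750 shifted base means gave such a solution, all 6 among the 150 between 3000 and 10000. That range holds CFL1, PHGDH, UHMK1, GANAB and MYC. Above a base mean of 10000, 12 of 150 gave such a solution. Genes with a base mean of at least 10000 were therefore left out of all values per library, a limit set after 1 such gene, MT-CO1, had shown an implausible division of its reads between the knockouts. This left out 169 genes, among them the called genes RPL13A, TXNRD1 and YWHAZ. RSEM estimates counts, so the recovered reads are its rounded estimates, and reads shared by near-identical genes, such as ribosomal protein pseudogenes and histone genes, may be divided between them.

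On the recovered reads, limma with a trended prior was run on log2(normalized count + 1) for genes with a mean of at least 1, which understates changes of low genes. Tested on simulated reads of 23126 genes in 2 against 2 libraries, limma recovered 80 of 100 genes changed 2-fold and 100 of 100 changed 4-fold, with 18 false calls. The simulated libraries shared a common profile, the mean of control A and the knockouts, at a single fixed dispersion. None lay as far from the rest as control B did, so these rates do not carry over to the real libraries. Alternatives were a pseudocount of 0.1, a mean of at least 10, voom, camera with a preset and an estimated correlation, fry, and leaving out each library in turn. GC content and length were those of the longest transcript of each gene in GENCODE, which gave values for 99.5% of 11463 genes with a base mean of at least 100. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.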

Results

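RNA sequencing compared cells labelled PANC-1, a human pancreatic ductal adenocarcinoma line, in which CFL1 had been knocked out with control cells under the same name, in 2 control and 2 knockout libraries of total RNA. CFL1 encodes cofilin-1, a protein that severs actin filaments. The series title ties CFL1 to N6-methyladenosine on super-enhancer RNA, to chromatin accessibility and to oncogene transcription, and the comparison asks which transcripts differ when CFL1 is lost. The authors' deposited table gives 1 result for each of 59885 genes, of which 30831 had a base mean above 0, and no column for single libraries. Whole reads per library were recovered from the base means, and below a base mean of 10000 these summed to 14329087 reads in control A, 14369205 in control B, 14649141 in knockout A and 12360041 in knockout B. The letters A and B are names only and do not map to the sample numbers in the labels. No label says that the libraries came from separate cultures or clones, so p-values measure the spread between these libraries, which may be technical.

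CFL1 (ENSG00000172757.12_3_CFL1) was lower in both knockout libraries than in both controls. Its recovered normalized count was 6276 in control A and 13761 in control B, against 2285 in knockout A and 2487 in knockout B. The log2 fold change of CFL1 in the authors' deposited table was -2.07, with a standard error of 0.454 and an adjusted p of 0.00168 from the DESeq2 Wald test. The controls differed from each other by 1.13 on the log2 scale at CFL1, and the knockouts by 0.12. With limma on the recovered reads, CFL1 had a log2 fold change of -1.96 and an adjusted p of 0.722, and without control B its log2 fold change was -1.40 with an adjusted p of 0.309.

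PHGDH, TNC and EGR1 were among the genes that rose, and CCL2, DKK1 and UHMK1 among those that fell. Of 16629 genes with an adjusted p in the authors' deposited table, 93 had a DESeq2 adjusted p under 0.05, 23 of them higher and 70 lower in the knockouts, and 78 had at least a 2-fold change. Reads of 38 of the 70 falling genes were found in control B alone, with no read in control A or in either knockout. By an unadjusted p under 0.05, the authors' deposited table also marks 606 genes as upregulated and 1743 as downregulated. With limma on the recovered reads of all 4 libraries 0 genes had an adjusted p under 0.05 and 495 had an unadjusted p under 0.05, and voom called 0 with 432 at an unadjusted p under 0.05. Without control A limma called 8305 genes, and without control B it called 0, with 3195 at an unadjusted p under 0.05.

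**Figure D1:**
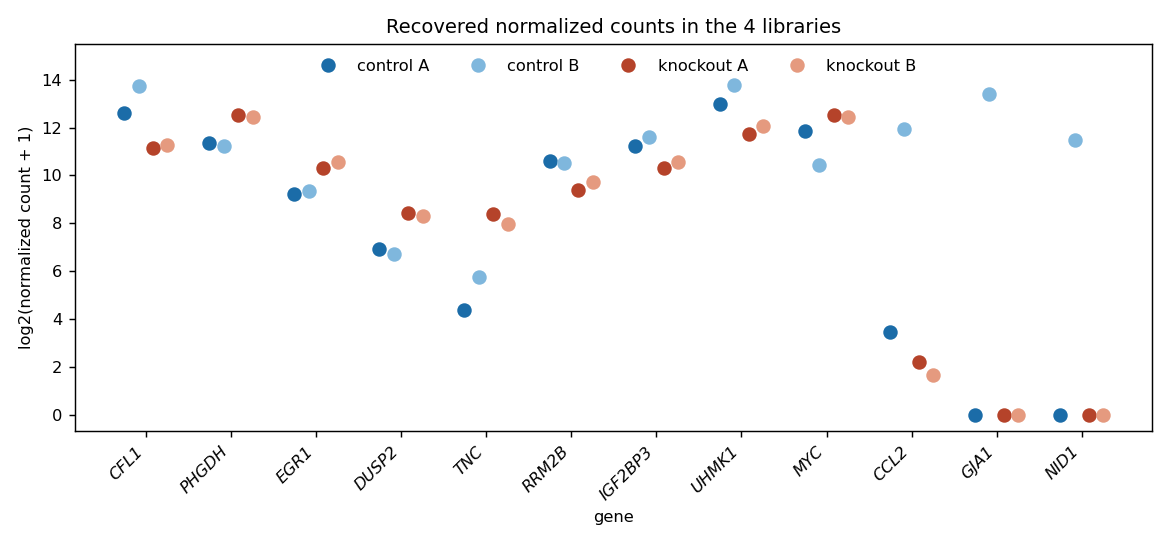
Recovered normalized counts of 12 named genes, as log2(normalized count + 1) on the vertical axis, with 1 point for each of the 4 libraries. CFL1 lies at 2285 and 2487 in the knockouts against 6276 and 13761 in the controls, whereas GJA1 has 10802 in control B and 0 in the other 3 libraries.

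Control B stood apart from the other 3 libraries. Across 17136 genes with a base mean of at least 10, Pearson's r of log2(normalized count + 1) was 0.71 between control A and control B, 0.98 between control A and either knockout, and 0.99 between the knockouts. These are correlations across genes, which are not independent replicates. Between the controls 3607 genes differed by more than 4-fold, against 148 between control A and knockout A and 128 between the knockouts. In control B 122 genes had no read although each of the other 3 libraries had a normalized count of at least 100, and 80 genes reached 100 in control B with no read elsewhere. LPL, which encodes lipoprotein lipase, had 7480, 7581 and 8253 normalized counts in control A, knockout A and knockout B, and 0 in control B.

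The clearest rise was of PHGDH, the first enzyme of serine synthesis from glycolysis. PHGDH had recovered normalized counts of 2627 and 2429 in the controls and 5928 and 5546 in the knockouts. Its log2 fold change in the authors' deposited table was 1.18 (standard error 0.172, DESeq2 adjusted p 1.01e-07). The largest rise was that of TNC, which encodes the matrix protein tenascin-C, with 22 and 48 recovered reads in the controls and 380 and 231 in the knockouts. The mean of the knockouts lay 3.79 above control A and 2.41 above control B on the log2 scale. For TNC the authors' deposited table gives a log2 fold change of 3.0, a standard error of 0.641 and a DESeq2 adjusted p of 0.00102. The phosphatase gene DUSP2, the stress gene NUPR1, the histone gene HIST1H3C and the small RNA gene SCARNA10 followed, with log2 fold changes of 1.55, 1.52, 1.46 and 1.35 in the authors' deposited table. GPT2, EGR1, CACFD1 and PTMS completed the 10 largest rises, with 1.19, 1.14, 1.09 and 1.06 in the authors' deposited table. The most abundant genes that rose were RPL13A, GANAB and RCN1, with log2 fold changes of 0.94, 0.66 and 0.75 in the authors' deposited table.

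Of the 22 rising genes with recovered reads, all 22 were higher in both knockouts than in both controls, and 10 were at least 2-fold higher than each control. In either direction, groups of 2 against 2 lie apart in 33.3% of cases by chance. Among 16455 tested genes 7406 did, 3933 of them with the knockouts higher. The 22 genes were called on these same libraries, so that they lie apart is no separate support.

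The falls split into genes read in several libraries and genes read in control B alone. Among the falls with a base mean of at least 100 in which both knockouts lay below both controls, the chemokine gene CCL2 had the largest, with 11 and 3493 recovered reads in the controls and 4 and 2 in the knockouts. AFAP1L2, MYEF2, CCL5, GPR137B, CMTM3, ZNF365 and LSR followed, with log2 fold changes from -7.17 to -5.42 in the authors' deposited table. Their normalized counts in control A were between 5.45 and 45.4. On the log2 scale their knockout means differed from control A by only -2.21 (MYEF2) to -0.71 (GPR137B). Against control B the differences were -7.76 (AFAP1L2) to -6.29 (LSR). DDAH1 and the Wnt antagonist gene DKK1 had more reads in control A, at 144 and 198 for DDAH1 against 500 and 3531, and at 186 and 204 for DKK1 against 473 and 3449. The most abundant genes that fell were TXNRD1, YWHAZ and UHMK1, with log2 fold changes of -0.72, -0.98 and -1.53 in the authors' deposited table. UHMK1 had 8093 and 14062 normalized counts in the controls and 3377 and 4285 in the knockouts.

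Of the called falls with no read in either knockout, the 10 with the highest control mean were GJA1, RP11-473I1.9, EREG, NID1, ACP7, ZNF518B, ARSI, KLHL4, CA8 and MMP2, all read in control B alone. GJA1, which encodes connexin 43, had 10802 normalized counts in control B and 0 in each other library. Against a floor of 3 reads over both knockouts its control mean is at least 3703-fold higher, and the -28.03 of the authors' deposited table for GJA1 is a fitted value and no bound. Of 42 called falls with no read in either knockout, 38 were read in control B alone, all with a standard error over 4 in the authors' deposited table. The others, BMP5, RSC1A1, AC005538.3 and FAM203B, have standard errors from 1.80 to 2.29. Of the 68 falls with recovered reads, 30 were lower in both knockouts than in both controls, and 21 were at least 2-fold lower than each control.

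**Figure D2:**
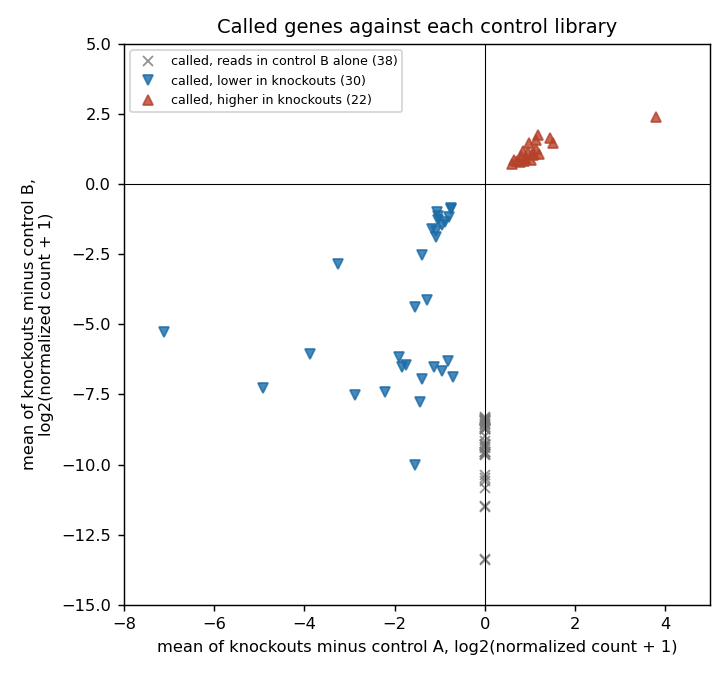
Difference between the mean of the knockouts and control A (horizontal axis) and control B (vertical axis) in log2(normalized count + 1), for called genes with recovered reads. The 38 crosses, genes read in control B alone, lie at 0 against control A, whereas the 22 rises lie above 0 on both axes.

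MYC, METTL3, YTHDC2 and KMT2A did not pass the test. MYC had a log2 fold change of 1.18 (standard error 0.536, DESeq2 adjusted p 0.339) in the authors' deposited table, with 3752 normalized counts in control A, 1370 in control B and 5969 and 5602 in the knockouts. For the methyltransferase gene METTL3, the reader gene YTHDC2 and the histone methyltransferase gene KMT2A, the authors' deposited table gives -0.25, 0.23 and 0.22 with DESeq2 adjusted p of 0.654, 0.765 and 0.691. Among 22 genes that write, erase or read N6-methyladenosine 0 rose and 1 fell, IGF2BP3, and 1 fell when adjusted over the list alone. IGF2BP3, an RNA-binding protein gene, had 2413 and 3107 in the controls and 1277 and 1515 in the knockouts. The list did not pass camera on the Wald statistic of the authors' deposited table, at an adjusted p of 0.111. Neither the 19 genes of H3K4 methyltransferase complexes nor the 24 enhancer coactivator genes had a called member, and their camera adjusted p were 0.904 and 0.992.

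Of 34 gene lists with at least 5 measured members, 16 passed camera at an adjusted p under 0.05 with a preset correlation of 0.01, 6 upward and 10 downward. On the recovered reads of all 4 libraries camera at the same correlation called 10 lists, 6 upward and 4 downward, the mitochondrial list being left untested for want of recovered members. By that test, 5 of these 6 upward lists and 0 of these 4 downward lists had a call in the same direction without control B, and 2 of the 6 and 4 of the 4 without control A. With an estimated correlation on the recovered reads 0 lists passed, the lowest adjusted p being 0.814, and fry called 0. Both rest on residuals with 2 degrees of freedom, in which the difference between the controls weighs most. They therefore cannot decide for or against a single list.

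Immediate early genes, which respond within minutes to growth factors and stress, passed camera upward at the preset correlation, but not with an estimated correlation or without control A. Of 16 measured members 2 rose, EGR1 and ATF3, 0 fell and 14 were not called, and 6 rose when adjusted over the list alone. The largest log2 fold change of a member was downward, -4.23 for ZFP36, which was not called. The mean over the members was 0.32, and 0.63 without ZFP36. EGR1 had 605 and 658 normalized counts in the controls and 1280 and 1507 in the knockouts. The list had a camera adjusted p of 1.62e-05, against 0.814 with an estimated correlation and 0.353 with fry. Its median was 0.95 on the log2 scale against control A and 0.70 against control B. The list of ribosomal protein genes had 0 called members of 46 and a camera adjusted p of 1.51e-08. RPL13A, a ribosomal protein gene called as a rise, is not in this list. Over the 28 members with recovered reads the median was 0.45 against control A and 0.46 against control B. With an estimated correlation the adjusted p of the ribosomal protein list was 0.814, as it was for the histone, mitotic, respiratory chain and DNA replication lists. Replication-dependent histone genes, whose RNA lacks a poly(A) tail, had 0 called members of 20, 10 that rose when adjusted over the list alone, and a camera adjusted p of 3.48e-09. Their median was 0.41 against control A and 1.11 against control B. In both knockouts 17 of 20 histone members were higher than in both controls. The same held for 11 of 16 immediate early and 19 of 28 ribosomal protein members. Mitotic genes and nuclear genes of the respiratory chain had 0 called members of 28 and of 30, with camera adjusted p of 0.00204 and 0.000982. DNA replication genes had 0 called members of 28 and a camera adjusted p of 0.00204, and on the recovered reads 0.00377 with all 4 libraries and 0.524 without control B. For immediate early, ribosomal protein, mitotic and respiratory chain genes, camera on the recovered reads gave adjusted p of 0.000571, 2.53e-06, 0.0296 and 0.00851 with all 4 libraries, and of 0.326, 0.158, 0.229 and 0.327 without control A, which ended those calls.

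For inflammatory and interferon-stimulated genes, the medians of the knockouts lay below control B and not below control A, a contrast between single control libraries that was not tested. Of 22 NF-kB and cytokine genes 2 fell, CXCL1, read in control B alone, and CCL2, 0 rose, and 9 fell and 1 rose when adjusted over the list alone. The list had a camera adjusted p of 8.88e-07, a median of -2.65 against control B and a median of 0.09 against control A. Interferon-stimulated genes had 0 called members of 28, a camera adjusted p of 0.00439, and medians of -1.71 and 0.15 against control B and control A. Camera on the recovered reads gave the NF-kB and cytokine list an adjusted p of 0.00357 with all 4 libraries and 0.741 without control B, and the interferon list 0.0712 and 0.741. The pancreatic cancer driver genes had 0 called members of 30 and a camera adjusted p of 0.0180, with medians of -0.75 against control B and -0.11 against control A. Integrin and focal adhesion genes, YAP and TAZ targets and genes of actin filament turnover, the last of which hold the partners of cofilin-1, had 0 called members of 26, 22 and 33 and camera adjusted p of 0.00202, 0.00949 and 0.00949. Their medians were -0.12, 0.03 and -0.05 against control A and -1.16, -0.65 and -0.83 against control B. Matrix genes had 2 called falls of 32, NID1 and MMP1, both read in control B alone, a camera adjusted p of 0.0333, and medians of 0.17 against control A and -0.73 against control B. Heat shock genes and genes of the mitochondrial genome had 0 called members of 16 and of 13, with camera adjusted p of 0.0333 and 0.000149, and the median of the heat shock genes was 0.03 against control A and -1.16 against control B. With an estimated correlation the adjusted p of the matrix genes was 0.846 and that of the other downward lists 0.814, the mitochondrial list being untested. The YAP and TAZ, driver, matrix and heat shock lists were not called by camera on the recovered reads of all 4 libraries, at adjusted p of 0.218, 0.133, 0.736 and 0.106, nor without control A, at 0.326, 0.0834, 0.356 and 0.0501.

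**Figure D3:**
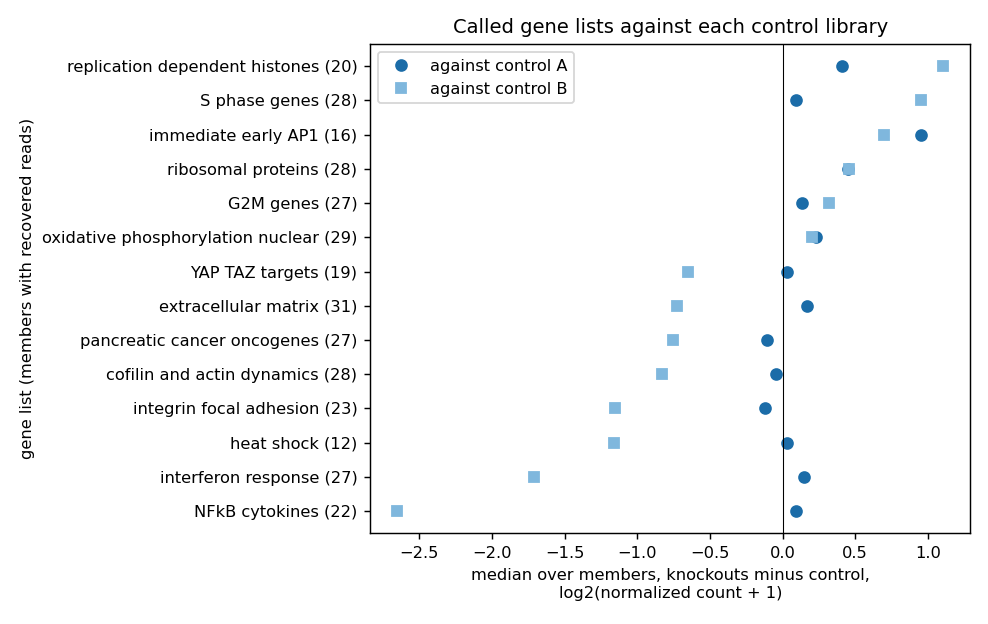
Medians over members of the knockout mean minus each control library, in log2(normalized count + 1), for the called lists described here with at least 5 members with recovered reads. NF-kB and cytokine genes lie at 0.09 against control A and -2.65 against control B, and immediate early genes at 0.95 and 0.70.

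Markers of other cell types gave no called list. Of 9 leukocyte and endothelial markers measured and 8 stromal fibroblast markers measured 0 were called, with camera adjusted p of 0.428 and 0.946. Neuroendocrine markers had 0 called members of 6 and a camera adjusted p of 0.982, and the 1 acinar marker measured, PRSS3, fell with 346 normalized counts in control B and 0 in the other 3 libraries. Classical pancreatic cancer markers had 1 called fall of 6, FOXA2, also read in control B alone, and basal-like markers 0 of 12, with camera adjusted p of 0.0957 and 0.593. The SRF and MRTF target, epithelial, mesenchymal, hypoxia, cholesterol synthesis, TGF-beta, Wnt and noncoding RNA lists did not pass, with camera adjusted p of 0.384, 0.255, 0.855, 0.428, 0.661, 0.0957, 0.478 and 0.778. Mesenchymal and Wnt lists had medians above 0 and means below 0, at 0.05 and -1.10 and at 0.21 and -1.03, and 1 member carried much of each mean, which was 0.20 without MMP2, read in control B alone, and -0.35 without SFRP1.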

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

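Tests on the recovered reads were all chosen after the data were seen. Of the planned settings, adjusting with no independent filtering, base means of at least 10 or 100 and an adjusted p under 0.01 gave 78, 91, 77 and 62 called genes against 93, and 68, 76, 61 and 55 with at least a 2-fold change against 78. On the recovered reads limma called 0 genes, and 0 with at least a 2-fold change, with a pseudocount of 1, a pseudocount of 0.1 and a mean of at least 10 (495, 472 and 259 at an unadjusted p under 0.05), and voom called 0 (432 at an unadjusted p under 0.05). Leaving out 1 library gave from 0 to 8305 called genes, and from 0 to 6756 with at least a 2-fold change. The high counts came without control A, where 71 of the 93 calls of the authors' deposited table were shared, and the 0 without control B, knockout A or knockout B (3195, 81 and 78 at an unadjusted p under 0.05). In these fits a lone library is assumed to vary like the other group.

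CFL1 stayed lower in every fit run, at a log2 fold change of -1.96 with limma, -1.96 with a pseudocount of 0.1, -1.96 with a mean of at least 10 and -1.95 with voom, and from -2.53 to -1.40 with 1 library left out. Its limma adjusted p ranged from 0.0261 without control A to 1 without knockout A. Gene lists called were 15 by ranks, 14 at a base mean of at least 100 and 16 by random lists, but 10 with a correlation of 0.05, 10 with camera on the recovered reads, 0 with an estimated correlation and 0 with fry, and from 7 to 12 with 1 library left out, 7 both without control A and without control B. The cause was not tested. Of 54 other named genes with recovered reads, limma on all 4 libraries ended the call of 41. The log2 fold changes of PHGDH, DUSP2 and EGR1 stayed at 1.18, 1.55 and 1.14, but those of CCL2, AFAP1L2 and GJA1 were -5.77, -4.59 and -6.70, against -9.42, -7.17 and -28.03 in the authors' deposited table. All 90 calls with recovered reads kept their sign with 4 libraries, and without control B 52 did, 22 rises and 30 of 68 falls. In these 52 both knockouts lay on the same side of both controls, and the other 38 had no read outside control B. The outcome without control B was therefore fixed and is no check of the calls.

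Alternatives that need a count test on deposited counts per library were not run. No paired analysis was possible because the deposited table carries no replicate numbers, and libraries recovered from it cannot be matched to those in the labels.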

Other observations

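Tests of explanations were chosen after the data were seen, and only those of GC content and length before their own outcome was. Outside the called lists, unfolded protein and ATF4 response genes divided by control. Of 26 measured members 1 rose, PHGDH, and 3 rose when adjusted over the list alone. Their median was 0.30 against control A and -0.68 against control B, and the list was not called on the deposited Wald statistic (camera adjusted p 0.247, upward, with a median of -0.18) or on the recovered reads of all 4 libraries (0.736). Without control B it was called upward at 0.000200, but without control A its direction was downward at 0.241, and with an estimated correlation on all 4 libraries its adjusted p was 0.860. Of 19 p53 targets 1 fell, RRM2B, with 1568 and 1485 normalized counts in the controls and 664 and 841 in the knockouts, and the list was not called on the deposited statistic (camera adjusted p 0.144) or on the recovered reads (0.308). Without control B it was called downward at 0.0328, but its adjusted p was 0.840 without control A and 0.814 with an estimated correlation, and its median was -0.18 against control A and -0.06 against control B.

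Control B differed from the other 3 libraries more than the knockouts differed from control A. Cells of another kind mixed into control B would leave abundant genes of the other libraries readable, but 122 genes at 100 or more in the other 3 had no read there, which argues against a mixture. That control B may come from other cells stays open. CDKN2A, CDKN2B and their neighbour CDKN2B-AS1 had no read in control B, and MTAP had 27.9 against at least 1249 elsewhere. In control A, knockout A and knockout B, CDKN2A had 906, 1553 and 1303 normalized counts and CDKN2B 437, 296 and 360. Homozygous CDKN2A deletion is known of PANC-1, so at this locus these reads argue against that line for the other 3 libraries, the knockouts included. Control B lacks these reads, as that line would, but silencing could give the same, so its own identity is open. The longest run of neighbouring genes lacking in control B alone was 6, however, in the protocadherin beta cluster, which silencing could also give, so deletion and silencing cannot be told apart here. Of 13 duplicate annotation entries of genes carried by both sex chromosomes, 13 had no read in control B while their partner entries did. The paired entries are identical copies, so this points to different counting of control B at those entries. Whether different counting reached other genes, such as near-identical histone genes or pseudogenes, was not tested.

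Of the 70 called falls, 38 had reads in control B alone. Control A had no read of these 38 either, so they set control B apart from control A as much as from the knockouts. This argues against the loss of CFL1 as their cause, although the controls contradict each other there and no further control decides. A mislabelled control A is argued against by CFL1, which lay 1.40 above the knockouts on the log2 scale, where the knockouts differed by 0.12. That the Wald test of a group at 0 under a very large dispersion gave these calls may be so, with a standard error over 4 for all 38. Called falls with no read in either knockout but reads in control A were BMP5, RSC1A1, AC005538.3 and FAM203B. Their standard errors were 2.29, 1.89, 1.80 and 1.97. A standard error over 4 thus went with control A at 0 too, and not with knockouts at 0 alone. The Wald test was not refitted at another dispersion, so its part in these calls stays open.

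The medians of immediate early and ribosomal protein genes lay above each control, with 12 of 16 and 19 of 28 members higher than control B, and GC content may contribute to the differences from control A. Across genes, Spearman's rho between GC content and the difference from control A was 0.26, 0.29 for the difference between the knockouts themselves and -0.02 for the difference from control B. After a running median over GC content and length was removed, the median difference from control A was 0.74 for immediate early genes (0.95 before) and 0.33 for ribosomal protein genes (0.45 before), which argues against the trend as the whole cause. Against control B the medians of the same members, 15 immediate early and 28 ribosomal protein genes at a base mean of at least 100, were 0.47 (0.55 before) and 0.50 (0.46 before). That CFL1 loss raised these genes stays a hypothesis, with 1 control library standing apart.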
